A study of Mus with 4 samples.

How the data were processed

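RNA from sorted liver DX5-negative NK cells of WT and dnTGFbRII mice was labelled and hybridised to Affymetrix arrays, per the labels' protocols, with 2 arrays in each genotype. Per the submitters' processing notes, the values were made with RMA and the Affymetrix Expression Console. The versions, the RMA variant (gene or exon level), the annotation release and the genome build are not given in the sources used here, so no coordinates are printed. The deposited table holds log2 expression values, 1 column per sample, whose array medians and quartiles nearly coincide (upper quartiles between 6.54 and 6.64). They were used as deposited with no further normalization. The table has no detection call, so a low value cannot be told from background. Samples were assigned to groups by the genotype in the labels, and replicate numbers were taken from the sample titles. At most 0.044% of values were identical between any 2 arrays, so no array was taken for a copy of another.

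Of the 72688 rows of the table, 32750 are paired with genes in the platform annotation, 30604 of them with exactly 1 gene and 2146 with several. The other 39938 rows are not listed there and are unnamed here. Symbols were updated through Entrez identifiers to a mouse reference gene table (assembly GRCm38.p6, used for names only), which matched 30294 of the one-gene rows. For each of 30142 genes the one-gene row with the highest mean over the 4 arrays was kept. For 355 genes there were several such rows, and in 0 of these did rows differ in sign with both differences beyond 0.5. Genes with a mean above 4.217, the median of all row means, were tested (16245 genes). Rows naming several genes were not used for gene values. For this reason 56 listed genes, Itga1 among them, are not reported here. Close copies within gene families, such as the Klra receptors, the Ly6 genes and the T cell receptor segments, can share probes, and their single values are uncertain.

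The 2 genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior, 2-sided, 2 residual and 2.54 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Genes at an unadjusted p under 0.05 and at least a 2-fold difference were also counted, as a description. Differences are dnTGFbRII minus WT on the log2 scale, and ± after a difference is the standard error of the fit.

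Gene lists for NK cell subsets, receptors, effector molecules, cytokine responses, TGF-beta signalling, metabolism, stress and other cell types of the liver (32 lists, 560 genes, 504 with a one-gene row) were compiled from general knowledge. Lists with at least 5 tested genes (27) were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 27 lists. The same test with a correlation estimated from each list, and fry, a rotation test of whether a list moves on balance one way, were run as alternatives. Members were also counted with p-values adjusted over the list alone. Several genes are in more than one list, among them Eomes, Ikzf2, Klrg1, Ctla4 and Cx3cr1, so the lists are not independent.

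The genes named in the text follow a rule: the 8 largest differences in each direction among annotated genes past the threshold or, where too few pass, with an unadjusted p under 0.01 and no overlap between the groups (predicted genes, pseudogenes and small RNAs passed over), 10 genes named in advance for NK cell identity and TGF-beta signalling, and up to 4 members of each list with the largest test statistics. Genes named outside it are said to have been chosen after their values were seen. The groups, the test, the lists, the naming rule and the alternative settings were chosen before the data were examined. Alternatives were a trended and robust prior, no filter and a filter at the 75th percentile of row means (6.583), repeated quantile normalization, median centring, averaging the probe sets of a gene, the replicate number as a block, a false discovery rate of 0.1, the other list tests, and each array left out in turn, where the lone array of a genotype is assumed to vary like the other genotype.

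The scripts were tested on simulated data for this comparison, with arrays drawn for the 16245 genes and 200 genes changed in each of 10 runs. limma at an adjusted p of 0.05 recovered 4.49% of genes changed by a log2 difference of 1, 77.7% of those changed by 2 and 91.8% of those changed by 3, with 53 false calls over all runs. The list test with the preset correlation made 0 calls in 270 tests of unchanged lists and found a list shifted by 0.4 in 10 of 10 runs, against 0 of 10 with the estimated correlation. The simulated genes vary independently, so that test does not show how the preset correlation behaves in lists whose genes vary together. The simulated arrays also lack the structure along the replicate number seen in the deposited arrays (r = 0.5105 between deviations of same-numbered arrays). The shares of genes recovered may therefore not hold for the deposited arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.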

Results

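Liver natural killer (NK) cells that do not bind the DX5 antibody were profiled on 4 Affymetrix arrays, 2 from wild-type (WT) mice and 2 from dnTGFbRII mice. All animals were female C57BL/6 mice aged 6 to 8 weeks. DX5 recognises the integrin chain encoded by Itga2, which circulating NK cells carry on their surface, and liver NK cells without it are regarded as tissue-resident. The dnTGFbRII line carries a dominant-negative form of TGF-beta receptor II and develops liver inflammation. The single comparison, dnTGFbRII minus WT, asked how DX5-negative liver NK cells differ between the genotypes. Nothing in the labels says that the 2 arrays of a genotype came from separate mice or sorts, so the p-values measure only the spread between these samples, which may be technical. The array medians lay between 4.20 and 4.26 on the log2 scale, and the number of arrays limits the precision of every value. Tgfbr2 itself measured 11.00 ± 0.11 in WT and 10.99 ± 0.10 in dnTGFbRII cells (SD, n = 2). Whether its mouse probes read the transgene is not known, so this value does not check the genotype.

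Some genes of circulating NK cells, among them Eomes, Ly6c2 and Klra7, and some of the T cell receptor complex, among them Cd3d and Cd3e, were higher in DX5-negative NK cells from dnTGFbRII mice, while others of both groups were not. Eomes, the T-box transcription factor of circulating NK cells, measured 6.80 ± 0.03 in WT and 9.59 ± 1.01 in dnTGFbRII cells (SD, n = 2), a 6.93-fold difference. Ly6c2, a Ly6C surface protein gene, went from 9.40 ± 0.56 to 12.07 ± 0.47, and Cd3d, a chain of the CD3 complex, from 10.85 ± 0.29 to 12.98 ± 0.30. As groups, type I interferon targets, T cell markers, lymphocyte transcription factors and circulating NK cell genes rose in dnTGFbRII cells, while dendritic cell markers and cholesterol synthesis genes fell, by a list test with a preset correlation between genes. With an estimated correlation no list passed, and the lowest adjusted p of the 27 lists was 0.357. In simulated arrays with independently varying genes, that form of the test found a shifted list in 0 of 10 runs. Missing its threshold, here and for each list below, therefore does not decide whether a shift holds.

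No single gene passed an adjusted p of 0.05 in limma among the 16245 genes tested, in either direction, and the lowest adjusted p was 0.725. At an unadjusted p under 0.05 there were 525 genes, 316 higher and 209 lower in dnTGFbRII cells, against 812 by chance. Of these, 80 were at least 2-fold higher and 29 at least 2-fold lower. Leaving out WT replicate 2 gave 6 lower genes past the adjusted threshold and 128 at least 2-fold lower, and leaving out WT replicate 1 gave 19 at least 2-fold lower. Leaving out dnTGFbRII replicate 2 gave 129 at least 2-fold higher. Arrays of the same replicate number deviated together (r = 0.5105), which the main fit counts as spread. The 525 genes, fewer than by chance, therefore do not show that genotype has no effect. With the replicate number as a block, 1467 genes had an unadjusted p under 0.05 in limma and 0 passed the adjusted threshold. What the number marks is not given in the labels. An exact 2-sided permutation test of 2 against 2 arrays cannot go below p = 0.333, so gene values are given with the standard error of the limma fit.

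Among annotated genes whose arrays did not overlap between genotypes and whose unadjusted p was under 0.01, the 8 with the largest positive log2 differences were Trav16d-dv11 (3.12 ± 0.33 SE), Eomes (2.79 ± 0.49), Ly6c2 (2.68 ± 0.37), Traj38 (2.65 ± 0.40), Klra7 (2.63 ± 0.45), Trav12d-2 (2.14 ± 0.46), Trav12-2 (2.13 ± 0.17) and Cd3d (2.13 ± 0.23). Trav16d-dv11, Trav12d-2 and Trav12-2 are variable segments and Traj38 a joining segment of the T cell receptor alpha locus, while Klra7 encodes the NK receptor Ly49G. The variable segments, Klra7 and Ly6c2 belong to families of close copies whose probe sets can share signal, so the values of single members are uncertain. The 8 genes with the largest negative differences were Styk1 (-1.15 ± 0.16), Tbc1d4 (-0.86 ± 0.20), Smpd5 (-0.86 ± 0.13), Bmpr2 (-0.83 ± 0.14), Swap70 (-0.70 ± 0.16), Klrc3 (-0.69 ± 0.13), Gcsam (-0.67 ± 0.14) and Gpr34 (-0.67 ± 0.13). Styk1 encodes a receptor pseudokinase, Bmpr2 the type II receptor for bone morphogenetic proteins, and Klrc3 the NK receptor NKG2E. The differences of these 16 genes kept their sign in all 172 values obtained under the alternative settings. Since the genes were chosen for no overlap between the groups, leaving out 1 array could not turn a sign. Only rescaling or averaging of probe sets could have done so, and the count is therefore no measure of stability.

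**Figure D1:**
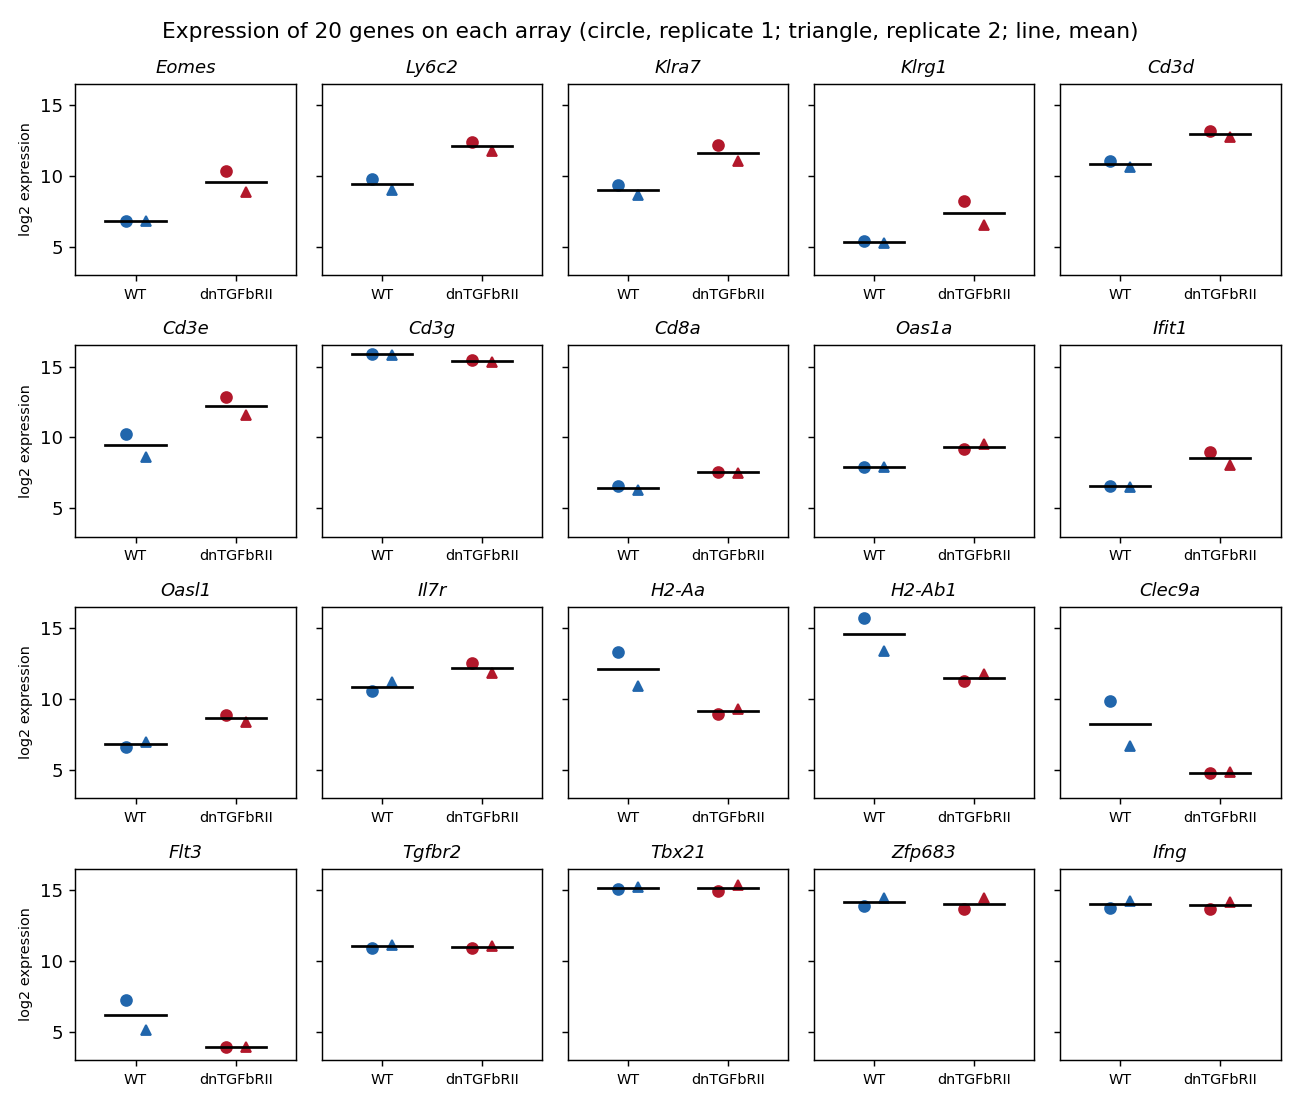
Log2 expression of 20 genes (y axis) on the 2 WT and 2 dnTGFbRII arrays (x axis), with replicate 1 as circles, replicate 2 as triangles and the group mean as a line. Eomes, Ly6c2, Klra7 and Cd3d lay higher on both dnTGFbRII arrays, H2-Aa, H2-Ab1, Clec9a and Flt3 lay lower with WT replicate 1 far above WT replicate 2, and Tgfbr2, Tbx21, Zfp683 and Ifng overlapped between the genotypes.

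Circulating NK cell genes rose in dnTGFbRII cells. Of 14 tested, 9 had positive differences, and the median was 0.34 (camera adjusted p = 0.00104, preset correlation; adjusted p = 0.452 with an estimated correlation). None of the 14 passed over all genes tested, and 4 passed when adjusted over the list alone. These were Eomes, Ly6c2, Klra7 and, in the other direction, Klra9 (-0.82 ± 0.20), which encodes the receptor Ly49I. Itga2, the DX5 antigen itself, differed by 0.50 ± 0.16, from 8.44 ± 0.17 in WT to 8.94 ± 0.16 in dnTGFbRII cells (SD, n = 2). Klrg1, a receptor of mature NK and effector T cells, differed by 2.03 ± 0.56. T cell markers moved with these genes, with a median difference of 0.48 over 13 tested genes.

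Liver-resident NK and type 1 innate lymphoid cell genes did not pass as a list (19 tested, camera adjusted p = 0.885), and their median (-0.13) and mean (0.07) differed in sign. Within this list, Il7r (1.31 ± 0.33), Ikzf2 (1.22 ± 0.21) and Itgb3 (0.66 ± 0.21) were higher and Tmem176b was lower (-0.41 ± 0.18) in dnTGFbRII cells, and 0 genes passed over all genes tested or when adjusted over the list alone. Zfp683, which encodes Hobit, a regulator of tissue residency, differed by -0.13 ± 0.34. Tnfsf10, which encodes TRAIL, differed by -0.38 ± 0.19, and Tbx21, which encodes T-bet, by 0.01 ± 0.20. NK cell receptor genes fell as a list, with 16 of 19 differences negative and a median of -0.09 (camera adjusted p = 0.0314, and adjusted p = 0.555 with an estimated correlation). That call was lost without WT replicate 2 (adjusted p = 0.994, with the direction turned), without dnTGFbRII replicate 1 (0.617) and after repeated quantile normalization (0.0764), and 0 of the 19 passed over all genes tested or when adjusted over the list alone. Klrc2 (-0.60 ± 0.15), Klrc1 (-0.34 ± 0.17) and Klri1 (-0.27 ± 0.12) were on the negative side and Klrb1f (0.45 ± 0.14) on the positive side. The cytotoxic granule and death ligand genes did not pass (18 tested, camera adjusted p = 0.736), with a median of -0.07 and a mean of 0.04. Gzmk, a granzyme, was the 1 member that passed when adjusted over the list alone (1.48 ± 0.24), against 0 over all genes tested.

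Type I interferon targets rose in dnTGFbRII cells with the lowest camera p of the 27 lists. Of 27 tested genes 25 had positive differences, the median was 0.39 and 16 lay higher on both dnTGFbRII arrays than on both WT arrays (camera adjusted p = 5.99e-15, and adjusted p = 0.357 with an estimated correlation). Adjusted over the list alone, 5 passed, against 0 over all genes tested. They were the antiviral genes Ifit1 (1.99 ± 0.31), Oasl1 (1.83 ± 0.23), Oas1a (1.41 ± 0.17) and Mx1 (0.63 ± 0.12), and Ifit2 (0.86), the last named after its values were seen. Oas1a measured 7.93 ± 0.02 in WT and 9.34 ± 0.25 in dnTGFbRII cells (SD, n = 2). Interferon-gamma targets also rose, with 16 of 24 differences positive and a median of 0.07 (camera adjusted p = 0.0498, and adjusted p = 0.514 with an estimated correlation). This call was lost without WT replicate 1 (adjusted p = 0.453), without WT replicate 2 (0.169) and without dnTGFbRII replicate 2 (0.661), and it missed the threshold with no filter on level (0.213), a trended prior (0.0555) or averaged probe sets (0.0622). Its 4 named members were Cxcl10 (1.59 ± 0.32), a chemokine that type I interferon also induces, Gbp3 (0.71 ± 0.16), Iigp1 (0.52 ± 0.18) and Ciita (-1.27 ± 0.44), the class II transactivator. Of the 24, 0 passed over all genes tested or when adjusted over the list alone. Ciita lay at 6.30 and 5.03 on WT replicates 1 and 2 against 4.43 and 4.37 on the dnTGFbRII replicates. Dendritic cell markers were likewise highest on WT replicate 1. Ifng itself differed by -0.08 ± 0.25.

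NF-kappaB targets rose, with 12 of 15 differences positive and a median of 0.28 (camera adjusted p = 0.000289, and adjusted p = 0.452 with an estimated correlation). Without WT replicate 2 (adjusted p = 0.0702) and without dnTGFbRII replicate 2 (0.441) this call was lost. Tnip1 (0.47 ± 0.15), Nfkb2 (0.42 ± 0.14), Relb (0.37 ± 0.14) and Tnfrsf4 (0.32 ± 0.14) led the list, and 0 of 15 passed over all genes tested or when adjusted over the list alone. Inhibitory receptors and ligands rose with 13 of 19 differences positive and a median of 0.18 (camera adjusted p = 0.0314, and adjusted p = 0.452 with an estimated correlation). The members went both ways, with Klrg1, Ctla4 (1.46 ± 0.32) and Lilrb4a (0.56 ± 0.15) higher and Btla (-1.30 ± 0.53) lower. Of the 19, 0 passed over all genes tested or when adjusted over the list alone. Btla lay at 6.81 and 5.39 on WT replicates 1 and 2 against 5.11 and 4.49 on the dnTGFbRII replicates. Dendritic cell markers, too, were highest on WT replicate 1, and T cell markers rose (median 0.48). The call held only without dnTGFbRII replicate 1 (adjusted p = 0.00147) among the 4 left-out arrays, at 0.085 without WT replicate 1, 0.215 without WT replicate 2 and 0.569 without dnTGFbRII replicate 2, and it missed the threshold with no filter on level (0.125) or a stricter one (0.095). Secreted cytokines and chemokines did not pass (14 tested, median 0.03, camera adjusted p = 0.674), nor did chemokine receptors and homing genes (14 tested, median 0.03, 0.247), where Itga4 differed by 0.69 ± 0.22. Cytokine receptors did not pass (18 tested, median 0.05, camera adjusted p = 0.0999). That list had a positive shift past the threshold with a stricter filter (adjusted p = 0.0132) and without dnTGFbRII replicate 1 (0.00265). Il2ra, the alpha chain of the interleukin-2 receptor, passed when adjusted over that list alone (0.96 ± 0.16) but not over all genes tested, and the interleukin-18 receptor chains Il18rap (0.54 ± 0.13) and Il18r1 (0.52 ± 0.13) did neither.

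Lymphocyte transcription factors rose, with 18 of 22 differences positive and a median of 0.20 (camera adjusted p = 1.67e-06, and adjusted p = 0.357 with an estimated correlation). Adjusted over the list alone, Eomes and Ikzf2, which encodes Helios, passed, against 0 of 22 over all genes tested. Bach2 (0.54 ± 0.12) and Lef1 (0.51 ± 0.13), both expressed in naive and memory T cells, followed, and T cell markers moved with this list (median 0.48). TGF-beta target genes did not pass (15 tested, 11 negative, median -0.10, camera adjusted p = 0.0661). With each array centred on its median the same list passed (adjusted p = 0.0446), as it did with no filter on level (0.0118) and without WT replicate 2 (0.00642). Pmepa1 (-0.44 ± 0.12), Itgae (-0.47 ± 0.18) and Id3 (-0.60 ± 0.29) were lower and Ctla4 was higher, and 0 of 15 passed over all genes tested or when adjusted over the list alone. TGF-beta receptors and SMADs did not pass (12 tested, median -0.03, camera adjusted p = 0.129). Bmpr2 was the 1 member that passed when adjusted over the list alone, against 0 over all genes tested, and Tgfbr1 differed by -0.37 ± 0.17.

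Markers of other cell types also moved with genotype. T cell markers rose, with 11 of 13 differences positive and a median of 0.48 (camera adjusted p = 3.53e-08, and adjusted p = 0.357 with an estimated correlation). Adjusted over the list alone, 7 passed, against 0 over all genes tested. Those on the positive side included Cd3e (2.78 ± 0.68), Cd3d, Cd8a (1.10 ± 0.16) and Cd40lg (0.65 ± 0.13). Cd3g, named after its values were seen, passed over the list alone in the other direction, from 15.85 in WT to 15.41 in dnTGFbRII cells. Dendritic cell markers fell, with all 12 differences negative and a median of -1.52 (camera adjusted p = 4.49e-09, and adjusted p = 0.452 with an estimated correlation), while 0 passed over all genes tested or when adjusted over the list alone. The class II chains H2-Ab1 (-3.05 ± 0.79) and H2-Aa (-3.01 ± 0.82), the dendritic cell receptor Clec9a (-3.48 ± 1.04) and the cytokine receptor Flt3 (-2.27 ± 0.69) had the largest test statistics. The WT arrays themselves were far apart, with H2-Ab1 at 15.72 and 13.40 in WT replicates 1 and 2 against 11.29 and 11.73 in the dnTGFbRII replicates. Without WT replicate 2, Clec9a passed over all genes tested (difference -5.04, limma adjusted p = 0.0452).

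Neutrophil markers rose, with 5 of 7 differences positive and a median of 0.38 (camera adjusted p = 0.0314, and adjusted p = 0.452 with an estimated correlation). Without WT replicate 2 the adjusted p was 0.271, and the call was also lost with no filter on level (0.0662) and after repeated quantile normalization (0.0526). Ngp, a granule protein gene, measured 3.83 ± 0.05 and 4.66 ± 0.39 in WT and dnTGFbRII cells (SD, n = 2), near the filter of 4.22, and 0 of 7 neutrophil genes passed over all genes tested or when adjusted over the list alone. Macrophage and monocyte markers (8 tested, median 0.19, camera adjusted p = 0.192), B cell markers (7 tested, 0.966) and hepatocyte markers (5 tested, median -0.10, 0.255) did not pass. Leaving out WT replicate 1 gave the macrophage list a positive shift (adjusted p = 4.15e-05) and the hepatocyte list a negative one (0.0084), and without WT replicate 2 the macrophage list leaned the other way (0.215). The B cell median (0.05) and mean (-0.24) differed in sign, with H2-Ob, a class II accessory gene, at -2.03 ± 0.62. Erythroid, endothelial and stellate, cholangiocyte, and type 2 and type 3 innate lymphoid cell markers had fewer than 5 tested genes and were not tested as lists. Kit, in the type 3 list, differed by 1.99 ± 0.27 and passed over its list of 2 alone but not over all genes tested. In the erythroid list Car2 differed by 0.48 ± 0.23, in the type 2 list Icos differed by 0.46 ± 0.19, and Pecam1 (0.25 ± 0.25) and Epcam (0.00 ± 0.12) overlapped between the genotypes.

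Cholesterol synthesis genes fell, with 14 of 15 differences negative and a median of -0.30 (camera adjusted p = 8.22e-06, and adjusted p = 0.452 with an estimated correlation). Fdps (-0.73 ± 0.27), Cyp51 (-0.59 ± 0.26), Idi1 (-0.58 ± 0.18) and Lss (-0.30 ± 0.14), enzymes of the pathway, had the largest test statistics, and 0 of 15 passed over all genes tested or when adjusted over the list alone. The list mean was highest on WT replicate 1, at 7.54 and 7.27 on WT replicates 1 and 2 against 7.02 and 7.13 on the dnTGFbRII replicates, and WT replicate 1 also had the highest dendritic cell markers. Cell cycle genes rose by a median of 0.12, with 18 of 26 differences positive (camera adjusted p = 0.0303, and adjusted p = 0.541 with an estimated correlation). This call was lost without WT replicate 2 (adjusted p = 0.893), without dnTGFbRII replicate 1 (0.288), with no filter on level (0.0681) and with a stricter filter (0.112). Plk1 (0.25 ± 0.15), Cdc20 (0.28 ± 0.20), Rrm2 (0.23 ± 0.14) and Ccna2 (0.20 ± 0.14) led it. Genes of the unfolded protein response fell by a median of 0.14, with 11 of 13 differences negative (camera adjusted p = 0.0314, and adjusted p = 0.546 with an estimated correlation). It was lost without WT replicate 1 (adjusted p = 0.185), WT replicate 2 (0.0845) or dnTGFbRII replicate 2 (0.821, with the direction turned), and after repeated quantile normalization (0.0558). Sdf2l1 (-0.55 ± 0.27) and the chaperones Hsp90b1 (-0.36 ± 0.22) and Canx (-0.23 ± 0.12) led that list. For these 2 lists, 0 genes passed over all genes tested or when adjusted over the list alone.

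Glycolysis and glucose uptake (16 tested, median 0.10, camera adjusted p = 0.0782), oxidative phosphorylation (21 tested, median 0.05, 0.367) and apoptosis regulators (14 tested, median -0.08, 0.247) did not pass, and 0 of their genes passed over all genes tested or when adjusted over the list alone. In glycolysis, Slc2a1, which encodes a glucose transporter, differed by 0.26 ± 0.17 and Hk2 by -0.38 ± 0.26. With a stricter filter (adjusted p = 0.0317) or without dnTGFbRII replicate 1 (0.0415) the glycolysis list passed with a positive shift. Bcl2 differed by -0.29 ± 0.13. Immediate early and heat shock genes, which respond to handling of cells, did not pass (17 tested, median -0.09, camera adjusted p = 0.255). For that list the direction depended on the dnTGFbRII arrays, with a positive shift without dnTGFbRII replicate 1 (adjusted p = 0.0435) and a negative one without dnTGFbRII replicate 2 (5.2e-05). Jun differed by -0.51 ± 0.34 and Nr4a1 by -0.48 ± 0.36, within the spread between arrays.

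**Figure D2:**
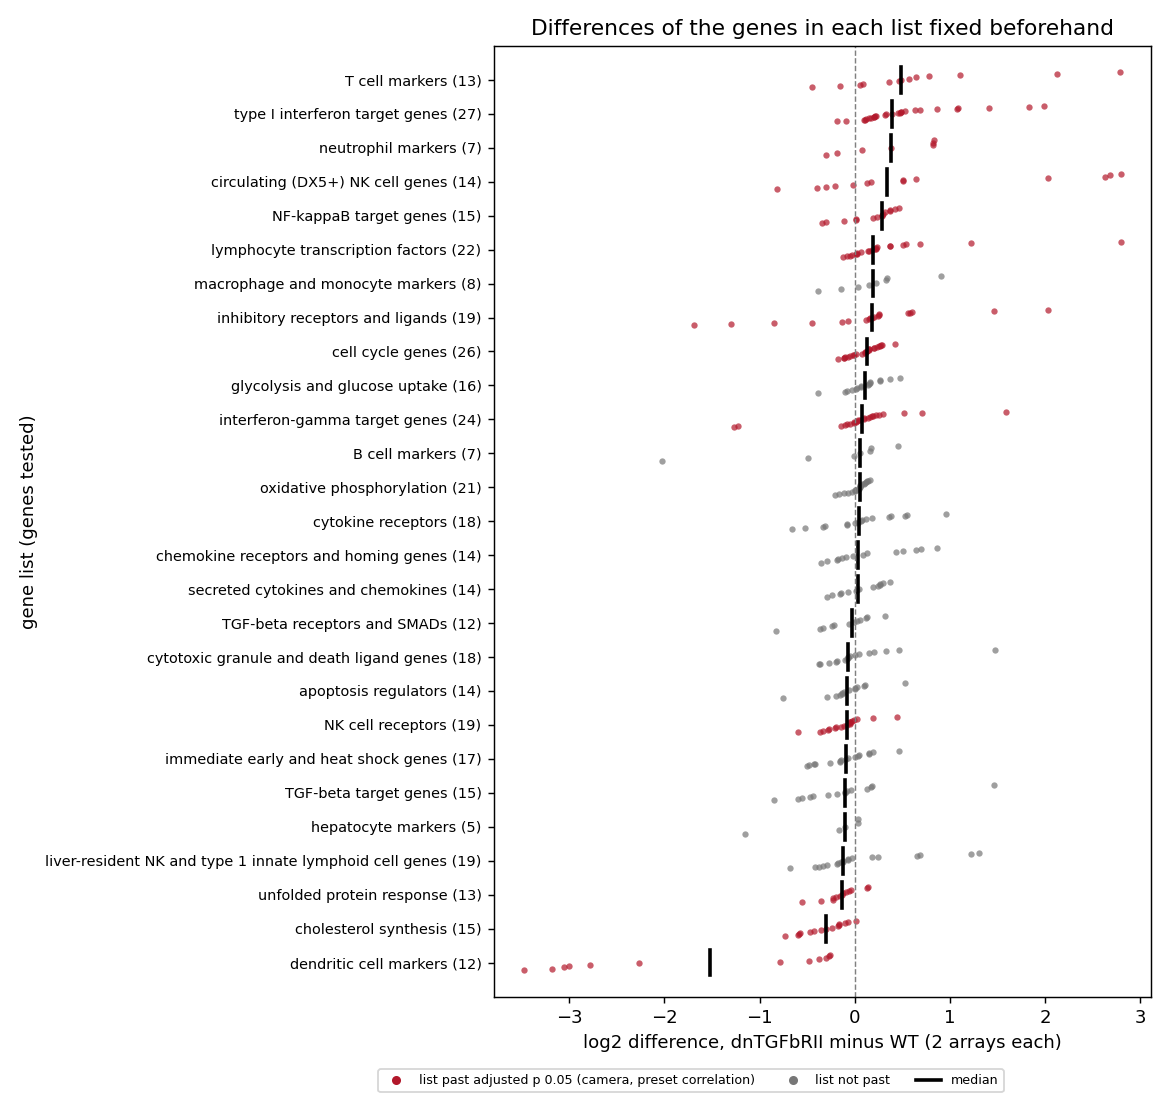
Log2 differences, dnTGFbRII minus WT (x axis, 2 arrays each), of the tested genes in the 27 gene lists (y axis, number tested in brackets). Each point is 1 gene, the black bar is the list median and red marks the 13 lists past an adjusted p of 0.05 in camera with the preset correlation, from dendritic cell markers (median -1.52) to T cell markers (median 0.48).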

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

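All alternatives named here were planned before the data were examined. With both arrays of each genotype kept, no setting gave a gene past the adjusted threshold, and a false discovery rate of 0.1 gave 0 higher and 0 lower. A trended and robust prior, repeated quantile normalization, median centring and averaged probe sets kept between 78 and 80 of the 80 genes at least 2-fold higher and 28 or 29 of the 29 lower. The filter at the 75th percentile kept 36 higher and 15 lower, because it removes dim genes. It left the B cell, hepatocyte, macrophage and neutrophil lists untested, and under it inhibitory receptors (adjusted p = 0.095) and cell cycle genes (0.112) missed the threshold. With no filter 5 lists of the 9 stayed higher, and interferon-gamma targets (0.213), inhibitory receptors (0.125), cell cycle genes (0.0681) and neutrophil markers (0.0662) did not. Repeated quantile normalization left 2 lower lists, without NK cell receptors (0.0764) and the unfolded protein response (0.0558), and moved neutrophil markers to 0.0526. Interferon-gamma targets lay at 0.0555 with the trended prior and at 0.0622 with averaged probe sets. For these changes the cause was not tested. The 13 list calls were made with the preset correlation, and 0 lists were higher and 0 lower when it was estimated from each list. The adjusted p was then 0.357 for type I interferon targets, transcription factors and T cell markers, 0.452 for circulating NK genes, inhibitory receptors, cholesterol synthesis, NF-kappaB targets, dendritic cell markers and neutrophil markers, 0.514 for interferon-gamma targets, 0.541 for the cell cycle, 0.546 for the unfolded protein response and 0.555 for NK cell receptors. With fry, too, 0 lists were higher and 0 lower, at 0.375 for type I interferon targets, transcription factors and T cell markers, 0.489 for circulating NK genes, 0.512 for cholesterol synthesis, 0.521 for interferon-gamma targets, inhibitory receptors, NF-kappaB targets, dendritic cell and neutrophil markers, and 0.657 for NK cell receptors, the cell cycle and the unfolded protein response. These 2 tests take the spread of each list from 2 residual degrees of freedom. The estimated correlation was 0.713 for dendritic cell markers and 0.0487 for type I interferon targets. For transcription factors (-0.0259) and neutrophil markers (-0.0443) it lay under the preset 0.01. A higher correlation therefore does not account for the loss of the calls on those lists. Fitting the replicate number as a block gave 1467 genes at an unadjusted p under 0.05, 0 past the adjusted threshold (lowest 0.126), and 83 genes at least 2-fold higher and 46 lower. Under the block inhibitory receptors lay at 0.0582 and glycolysis passed at 0.0256, and it changed no other call. Deviations from the group mean correlated between arrays of the same number (r = 0.5105), but the labels do not say what a number marks and there are only 2 pairs. In each fit with 1 array left out, the lone array of its genotype is assumed to vary like the other genotype. Type I interferon targets, T cell markers, transcription factors, circulating NK genes, dendritic cell markers and cholesterol synthesis kept their calls in all 4 of these fits. From 0 to 6 genes were lower past the adjusted threshold, the 6 being Alox5ap, Cd209a, Clec9a, H2-DMb1, Il1r2 and Plbd1 without WT replicate 2. Genes at least 2-fold higher ranged from 72 to 129 and lower from 19 to 128, and higher lists from 4 to 11. The adjusted p ranged from 3e-05 to 0.441 for NF-kappaB targets, 0.000226 to 0.994 for NK cell receptors, 0.00265 to 0.661 for interferon-gamma targets, 0.00147 to 0.569 for inhibitory receptors, 0.000156 to 0.893 for the cell cycle, 0.000153 to 0.821 for the unfolded protein response and 0.00283 to 0.271 for neutrophil markers. NK cell receptors turned direction without WT replicate 2 and the unfolded protein response without dnTGFbRII replicate 2. Immediate early genes ranged from 5.2e-05 to 0.453 and passed upwards without dnTGFbRII replicate 1 (0.0435). The cause of these changes was not tested. Of 1414 values of the 133 named genes under alternatives, 28 had the other sign, among them values of Tgfbr2, Tbx21, Ifng and Zfp683, whose differences were near 0. The largest difference to turn was that of Lyz2, from 0.90 to -0.10 without WT replicate 2.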

Other observations

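Segments of the T cell receptor alpha and beta loci lay higher on the dnTGFbRII arrays as a family, described after the values were seen. Of 83 tested variable segments 60 were higher on both dnTGFbRII arrays than on both WT arrays and 4 were lower, with a median log2 difference of 0.57 (interquartile range 0.34 to 1.06). The median was 0.57 for 63 alpha variable segments and 0.85 for 13 beta variable segments, 12 of them higher on both, against 0.10 for 3 gamma and -0.01 for 4 delta segments. The alpha group takes in segments named for both alpha and delta, such as Trav16d-dv11, so these medians do not cleanly part alpha from delta. Of the gamma segments Trgv3 (0.61 ± 0.22), chosen after its values were seen, was higher on both, and no test compared the loci. Single segments are near copies of each other and share probes, so the family and not its members is described. The Ly6 family had a median of 0.19 and 6 of 11 members higher on both arrays. Among them were Ly6c1 (0.92 ± 0.13 SE) and Ly6a2 (1.13 ± 0.29), but also Ly6e (0.17 ± 0.12) and Ly6g6g (0.09 ± 0.12), all 4 chosen after their values were seen. Over all genes tested, 12.6% were higher on both dnTGFbRII arrays and 14.5% lower on both.

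The Klra family, which encodes the Ly49 receptors, went both ways, with 3 of 8 members higher on both dnTGFbRII arrays and 4 lower. Klra6 (1.29 ± 0.46) and Klra16 (1.05 ± 0.24), chosen after their values were seen, lay with Klra7 on the positive side, and Klra9, at 14.14 in WT and 13.32 in dnTGFbRII cells, on the negative side. Of the 9 tested class II genes of the major histocompatibility complex, 8 were lower on both arrays, with a median of -2.38. H2-Eb1, chosen after its values were seen, measured 14.40 and 11.36 in WT and 10.07 and 9.34 in dnTGFbRII cells. No median of these families changed sign after repeated quantile normalization or median centring, where the class II median lay at -2.35 and -2.36. None of these genes passed over all genes tested.

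Explanations for 3 patterns were tested with the other values of the series, and of these tests only the one on macrophage markers was chosen after the result was seen.

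The rise of T cell markers and of alpha and beta T cell receptor segments may come from T cells among the sorted dnTGFbRII cells, since the labels name DX5 and no CD3 gate. The test took 8 T cell genes, all from the T cell marker list itself, so that it partly restates the rise of that list. Of these, 4 (Cd5, Cd6, Cd8b1, Cd28) were higher on both dnTGFbRII arrays and 4 (Cd4, Themis, Trat1, Bcl11b) were not, which does not decide it. Cd6 (3.65 in WT and 3.82 in dnTGFbRII cells) and Cd8b1 (3.91 and 4.24) had means over the 4 arrays under the filter, as did Themis. Their values cannot be told from background. Bcl11b was lower on both dnTGFbRII arrays (9.32 in WT and 9.16 in dnTGFbRII cells), and Cd4 lay at 4.76 in WT and 4.82 in dnTGFbRII cells. None of the 8 genes was in a list other than the T cell markers, 5 had a WT mean above the filter, and Cd3g, the list member with the highest probe signal, which does not rank transcripts between genes, went from 15.85 in WT to 15.41 in dnTGFbRII cells. Signal shared between dim variable segments in general was argued against, because immunoglobulin segments had 0.095 of the median difference of T cell receptor segments. That ratio does not cover signal shared among near copies within the T cell receptor loci, which was not tested and may raise the number of higher segments. T cell receptor and CD3 gene expression within NK cells of the dnTGFbRII liver, or T cells carrying NK receptors in the sort, remain open and were not tested.

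Higher Eomes, Ly6c2 and Klra7 could come from circulating (DX5+) NK cells among the sorted dnTGFbRII cells, which the DX5-negative gate should remove. Of 8 genes from the circulating NK list itself, 5 (Itga2, S1pr5, Cma1, Cx3cr1, Klrg1) were higher on both dnTGFbRII arrays and 3 (Itgam, S1pr1, Irf8) were not, so the test does not decide it. Cma1 (3.56 in WT and 4.12 in dnTGFbRII cells) had a mean over the 4 arrays under the filter, and S1pr5 (4.06 and 4.57) lay under it in WT. Itgam was lower on both dnTGFbRII arrays (8.35 in WT and 8.05 in dnTGFbRII cells). Klra9 and Klra3 were lower on both arrays (Klra3, chosen after its values were seen, by 0.39), which an added share of cells richer in these genes would not explain. Of the 8 genes, 4 are also in a list other than this and 5 had a WT mean above the filter, and Eomes, Ly6C and KLRG1 are also made by effector T cells. A gain of some circulating NK cell genes by the resident cells themselves remains open and was not tested.

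Lower dendritic cell genes could reflect dendritic cells in the WT sorts, more in WT replicate 1, and no result here argues against this. Of 8 further genes taken for dendritic cells, 7 (H2-DMb1, H2-DMb2, Naaa, Wdfy4, Plbd1, Fgd2, Ifi30) were lower on both dnTGFbRII arrays and higher in WT replicate 1 than in WT replicate 2, all but H2-DMa. None of the 8 is in another list and all 8 had a WT mean above the filter. H2-DMa, H2-DMb1 and H2-DMb2 belong to the class II genes described above, and the dendritic cell list varied together (estimated correlation 0.713). The 7 are therefore not independent results. Nor can they tell dendritic cells from other cells with class II genes, since H2-Ob of the B cell list fell too (-2.03). The highest probe signals of the list were those of Itgax, chosen after its values were seen, at 16.16 and 16.37 in WT and 15.61 and 16.32 in dnTGFbRII cells, a gene NK cells also express and without this pattern, and of H2-Ab1, at 15.72 and 13.40 against 11.29 and 11.73. The macrophage and monocyte markers, with a median difference of 0.1883, gave no general loss of myeloid cells, but this rests on WT replicate 2, since their list means were 6.31 and 5.54 in WT and 5.93 and 6.28 in dnTGFbRII cells and the list leaned down without that array, so WT replicate 1 was high in these markers too and the question stays open. Whether dendritic cells differ between the livers, the sorts or by chance between these arrays remains open, and class II expression by NK cells was not tested.

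The number of lists past the threshold may itself depend on how the arrays are grouped. Only 3 ways exist to split 4 arrays into 2 and 2, too few for a share under 0.05, and 1 of the 3, the genotype, gave as many as 13 lists, while the highest other split gave 7. The split by replicate number gave 1 list but 3835 genes at an unadjusted p under 0.05, against 525 for genotype and 99 for the remaining split, with 0 past the adjusted threshold in each. That count points to a structure of the samples along the replicate number, whose meaning the labels do not give. Hybridisation controls averaged 11.29 and 11.31 on the arrays numbered 1 and 11.54 and 11.70 on those numbered 2, and thus followed that number and not genotype.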
